A study of Mus musculus with 12 samples.

How the data were processed

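Whole lung RNA from 12 mice was measured on a NanoString nCounter innate immune panel, which counts barcoded probes bound to RNA without amplification. Per the labels' protocols, littermate wild type mice (labelled B6) and Chil4-deficient mice received PBS or DRA allergens into the nose 2 times per week for 8 weeks; the labels do not expand DRA, and they describe the deficient mice both as knockdown and as KO. The groups are B6_PBS (n = 2), B6_DRA (n = 5) and KO_DRA (n = 5), taken from the sample names, and no Chil4-deficient mice given PBS were analysed here. The sample sheet gives the 12 samples 12 different sample numbers under 1 experiment code, so no batch could be compared. Replicate numbers run from 1 to 12 and are never shared between groups.

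The authors deposited whole-number counts per probe for 734 endogenous probes, 20 housekeeping probes, 8 negative and 6 positive controls, with a lowest value of 1. The housekeeping probes were recognised from the order of the deposited table, which starts its alphabet again after the endogenous probes. A second deposited table and the series matrix hold the same counts multiplied by 1 factor per library, a signal scaled by the authors; the factors equal, apart from a constant, the inverse geometric mean of 17 of the 20 housekeeping probes, as found by a search over 1048575 subsets, with Edc3, Gusb and Polr1b left out. The submitters' processing notes name R 4.2.0, edgeR and limma without their roles. Background and export settings are not given in the sources used here. Of the panel's gene names, 744 are RefSeq symbols, 9 matched through a synonym and 1 did not match, in a table of the GRCm38.p6 assembly used for names and neighbours alone.

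The raw counts were tested with edgeR 4.0.16 in R 4.3.3: control probes were removed, probes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, TMM factors were computed, and 1 quasi-likelihood model with a mean per group was fitted to all 12 libraries with 9 residual degrees of freedom. Of the endogenous genes, 665 were tested, two-sided, with Benjamini-Hochberg adjustment over those genes and a threshold of 0.05. Standard errors are the log2 fold change over the square root of the quasi-likelihood F. CPM values use TMM-scaled library sizes, and their log2 uses a prior count of 2. Where a group lay below background, taken as the mean plus 2 SD of the negative controls, a fold is given as a lower bound against that level.

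Gene lists were written from textbook knowledge before the data were examined. Whole lung holds all the cell types whose markers were listed, so a shift of a marker list can reflect cell numbers. Of 30 lists, 27 had at least 3 members past the filter, called measured here, and were tested with fry in limma 3.58.1, whose p tests whether members move on balance one way and does not compare a list with other genes; 3 members were found under another symbol of the same gene (Ear11 as Rnase2a, C5 as Hc, Ccn2 as Ctgf). The chitinase list had 2 measured members, the airway epithelial list 1 and the erythrocyte list 0. Some genes sit in more than 1 list, so lists that pass are not separate findings. Named genes followed a rule set at the same time: the 12 highest and 12 lowest log2 fold changes past the threshold, up to 4 members of each list past fry, up to 2 members with the smallest p of lists mentioned with no member past the threshold, the 5 smallest p where fewer than 5 genes passed, the chitinase-like genes, and in the genotype comparison a fixed set of type 2 genes. It also takes in genes of the closing observations. Chil1 is not on the panel, and Il5, with 1 to 11 counts, did not pass the filter.

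Total endogenous and housekeeping counts per library ran from 320290 to 673201, and negative controls averaged 2.75 to 5.63 counts. Chil3, Chil4 and Retnla together took 2.79% to 43.6% of the counts. No pair of libraries of 1 group agreed within sampling noise; the closest pair, B6_PBS 1 and 2, had a chi-square of 5.33 per degree of freedom. Labels name mice but do not otherwise describe how libraries were prepared, so p-values measure the spread between these samples.

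The procedure was tested on data simulated from each gene's mean over all libraries, with the real dispersions and library sizes. Per comparison there were 10 draws with 200 changed genes, over 663 genes. For B6_DRA against B6_PBS it recovered 29.6% of genes changed 1.5-fold, 69.7% of those changed 2-fold and 94.1% of those changed 4-fold. For KO_DRA against B6_DRA the shares were 49.9%, 83.3% and 97.7%, and for KO_DRA against B6_PBS 26.6%, 62.7% and 94.1%. Simulated genes vary independently of one another, so these shares leave out swings that many genes share in 1 animal. Genes near background in only some groups were drawn at higher counts there than measured. Fewer changed genes would face a stricter threshold, so the shares can overstate what the real comparisons recover. Alternatives were other size factors, housekeeping scaling, library size alone, other filters, DESeq2 1.42.0, limma-voom, robust fitting, fits of only the 2 groups compared, the authors' scaled values and the series matrix values with limma after adding 1, camera in place of fry, and each library left out in turn.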

Results

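The innate immune gene expression of whole mouse lung was measured in 12 libraries: wild type mice given PBS (B6_PBS, n = 2), wild type mice given DRA allergens (B6_DRA, n = 5) and Chil4-deficient mice given the same allergens (KO_DRA, n = 5). Counts per library were 389757 and 392701 in B6_PBS, 367744 to 673201 in B6_DRA and 320290 to 658293 in KO_DRA. A first principal component of log2 CPM held 73.1% of the variance. On it the B6_PBS libraries lay at -18.46 and -17.19, and the B6_DRA libraries at 6.86 to 13.84 except B6_DRA 5 at -2.54. The KO_DRA libraries lay at -12.92 to -0.11 except the library labelled KO_DRA 8 at 13.61.

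Chil4, the targeted gene, encodes a secreted chitinase-like protein that lacks chitinase activity, and Chil3 is its near-identical neighbour on the chromosome. The Chil4 probe gave 5121 and 4406 counts in B6_PBS. It gave 89957, 56481, 13020, 79387 and 60176 counts in B6_DRA 3 to 7. In KO_DRA 9 to 12 it gave 8221, 5676, 24313 and 12198 counts, but the library labelled KO_DRA 8 gave 111850, the highest of all 12. If the probe reads the altered gene, the targeted gene goes against that label, but not against that label alone. KO_DRA 9 to 12 stood above both B6_PBS libraries as well, so no library labelled KO_DRA lacked the signal. KO_DRA 11, at 24313, also stood above B6_DRA 5, at 13020. In CPM KO_DRA 12, at 32590, did too, with B6_DRA 5 at 30080. Chil4 in CPM was 140700 ± 73400 (SD, n = 5) in B6_DRA and 74280 ± 103000 (SD, n = 5) in KO_DRA. The log2 fold change of KO_DRA against B6_DRA was -0.92 (SE 0.799, adjusted p = 0.53 by edgeR), and an exact two-sided permutation test of log2 CPM gave p = 0.135, where the smallest possible was 0.0079. Without the library labelled KO_DRA 8 the log2 fold change was -2.27 (adjusted p = 0.0403).

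Chil4 and Chil3 counts kept nearly 1 ratio in every library, from 0.771 to 0.899, while Chil3 itself spanned 26.4-fold. The log2 ratio differed between KO_DRA and B6_DRA by -0.06 (exact two-sided permutation p = 0.183). Where the Chil4 probe binds, and which part of the gene was altered, are not given in the sources used here, so this count checks the genotype only if the probe reads the altered part and not Chil3.

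**Figure D1:**
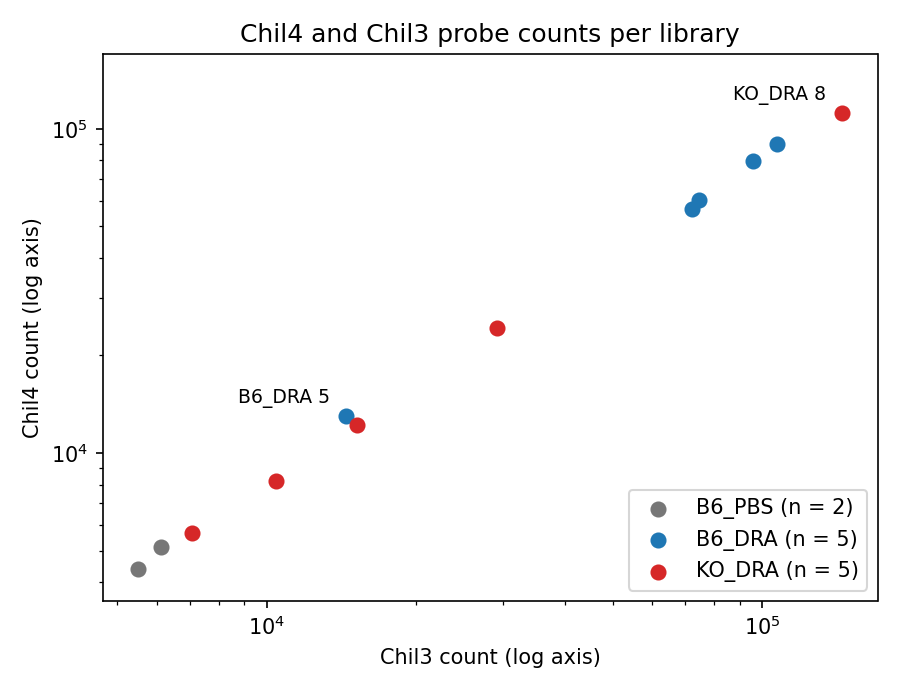
Chil4 count (vertical, log axis) against Chil3 count (horizontal, log axis) in each library, coloured by group. The library labelled KO_DRA 8 has the highest counts of both, 111850 for Chil4 and 145039 for Chil3, and B6_DRA 5 has the lowest Chil4 count of its group, 13020.

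The first comparison asked what the allergens changed in wild type lung. Genes listed for alternatively activated macrophages, cells induced by type 2 cytokines, rose steeply. Whole lung counts do not show which cells made the RNA. Retnla, a secreted product of these macrophages, rose 43.3-fold, from 1853 ± 227 CPM (SD, n = 2) to 80230 ± 32100 CPM (SD, n = 5; log2 fold change 5.44, SE 0.911, adjusted p = 0.00482), and stood above both B6_PBS libraries in 5 of 5. Arg1, which encodes arginase, rose 15.8-fold and Chil3 15.4-fold. Mmp12, the macrophage elastase gene of the matrix list, rose 125-fold, or 228-fold without B6_PBS 1 and 83.1-fold without B6_PBS 2. It was not past the test in either case, which sets it apart from no other gene in these fits. Of the 19 measured genes of alternatively activated macrophages, 12 rose and none fell, or 14 when adjusted over the list alone (fry adjusted p = 0.0255). Camera, which compares a list with the other genes, gave adjusted p = 0.00177 with a preset and 0.497 with an estimated correlation. Wherever an estimated correlation is named below, the test is camera.

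Eosinophil genes and the chemokines that draw eosinophils rose in the same libraries. Prg2, the eosinophil granule major basic protein, rose at least 11.7-fold and Rnase2a, an eosinophil-associated ribonuclease, at least 146-fold, both against B6_PBS levels below background. Ccr3, the receptor for eotaxins, rose 10.3-fold. Of 8 measured eosinophil markers, 6 rose, also when adjusted over the list alone (fry adjusted p = 0.00854). Of 10 chemokines of type 2 inflammation, 8 rose, or 9 when adjusted over the list alone (fry adjusted p = 0.0025). Ccl8 rose 32.4-fold, the eotaxin genes Ccl11 and Ccl24 rose 12.9-fold and 8.35-fold, and Ccl9 rose 10.5-fold. Ccl24 rose 13.04-fold without B6_PBS 1 and Ccr3 17.8-fold without B6_PBS 2. Neither was past the test, which sets them apart from no other gene in these fits. For both lists camera adjusted p = 0.497 with an estimated correlation.

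Of the type 2 cytokine genes and their receptors, Il33, an epithelial alarmin, rose 2.54-fold from 1216 ± 149 to 3095 ± 656 CPM (SD, n = 2 and 5; adjusted p = 0.0171 by edgeR), and its receptor gene Il1rl1 rose 3.63-fold. Il13 rose at least 2.57-fold and Il5ra at least 3.28-fold over B6_PBS levels below background. In this list, which also holds Areg, Gata3 and Stat6, 4 of 10 genes rose, or 5 with 1 lower when adjusted over the list alone (fry adjusted p = 0.00968; adjusted p = 0.497 with an estimated correlation). In the list of neutrophil chemokines and the IL-17 pathway, the chemokine genes Cxcl5, Cxcl1 and Cxcl3 rose 25.9-fold, 6.39-fold and 4.58-fold. The growth factor gene Csf2 rose 2.57-fold, while Cxcl2 and Il17ra did not pass. Without B6_PBS 1, Cxcl1 rose 10.2-fold, not past the test, which sets it apart from no other gene in that fit. In all, 4 of 6 members rose, also over the list alone (fry adjusted p = 0.0266, camera adjusted p = 0.497 with an estimated correlation). Of 10 neutrophil markers 1 rose and the list did not pass (fry adjusted p = 0.9).

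Antigen presentation and complement genes rose together. Of 12 measured genes of MHC class II presentation, 11 rose, also over the list alone (fry adjusted p = 0.0025; adjusted p = 0.497 with an estimated correlation). H2-Ab1, a class II chain, went from 5871 ± 525 to 13700 ± 1460 CPM (SD, n = 2 and 5), H2-Eb1 rose 2.50-fold, the costimulator gene Cd80 2.77-fold and the invariant chain protease gene Ctss 4.54-fold. Of 8 complement genes, 6 rose and 1 fell, or 7 and 1 over the list alone (fry adjusted p = 0.0025; adjusted p = 0.497 with an estimated correlation). C1qa, C1qb and C1qc, the subunits of C1q made by tissue macrophages, rose 3.61-fold, 3.96-fold and 3.18-fold.

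Markers of monocytes and interstitial macrophages rose in 9 of 15 genes with 1 lower, also over the list alone (fry adjusted p = 0.00512), and dendritic cell markers in 6 of 12 with 1 lower, or 7 and 1 over the list alone (fry adjusted p = 0.0266). T cell markers rose in 3 of 6 genes, also over the list alone (fry adjusted p = 0.00342). Among these, the checkpoint receptor gene Ctla4 rose by 2.58 on the log2 scale, Pdcd1 3.78-fold and Icos 2.20-fold. The other members, Cd28, Cd247 and Cd27, did not pass. Fc and C-type lectin receptors rose in 4 of 8 genes, or 5 over the list alone (fry adjusted p = 0.00968), with Cd209e at least 5.36-fold higher. Adhesion and trafficking genes had 10 of 23 higher and 3 lower, when adjusted over the list alone as well (fry adjusted p = 0.00189), but the list ran lower with library size alone (fry adjusted p = 0.739); Ccl20 rose 5.13-fold. Eicosanoid genes rose in 6 of 11, when adjusted over the list alone as well (fry adjusted p = 0.00189), but this list too ran lower with library size alone (fry adjusted p = 0.838); the lipoxygenase gene Alox15 rose 17.1-fold. For each of these 6 lists camera adjusted p = 0.497 with an estimated correlation.

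Endothelial markers fell, with 5 of 8 lower, or 7 over the list alone (fry adjusted p = 0.0337, camera adjusted p = 0.497 with an estimated correlation). In whole lung such a fall can reflect cell numbers, which these counts do not separate from expression per cell. Tek, an angiopoietin receptor gene, fell from 3697 ± 323 to 1851 ± 340 CPM (SD, n = 2 and 5, adjusted p = 0.0176 by edgeR). Thbd, Flt1 and Cdh5 fell by 1.03, 0.95 and 0.94 on the log2 scale. Among the genes past the test, the lowest besides Thbd were Col12a1 (log2 fold change -1.63), the immediate early gene Fosb (-1.62), the metalloprotease gene Adamts9 (-1.33), Cxcl14 (-1.20), the metalloproteinase inhibitor gene Timp3 (-1.14), Sphk1 (-1.13), Kitl (-1.08), Hpgd (-1.08), Vegfa (-1.06), Bmp6 (-1.01) and Gata2 (-1.01).

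In all, edgeR called 278 of 665 genes, 160 higher and 118 lower; 355 had an unadjusted p under 0.05, where chance gives 33.2. The split depends on scaling: library size alone gave 57 higher and 222 lower, housekeeping scaling 163 and 72, and the authors' scaled values 169 and 61, with median shifts over all genes of -0.63, 0.08 and 0.09. Without either B6_PBS library 0 genes passed, and without B6_DRA 3, 4, 6 or 7 the counts were 128, 176, 158 and 136. The 14 lists became 5 with library size alone. Camera called 11 lists with a preset correlation and 0 with an estimated correlation.

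**Figure D2:**
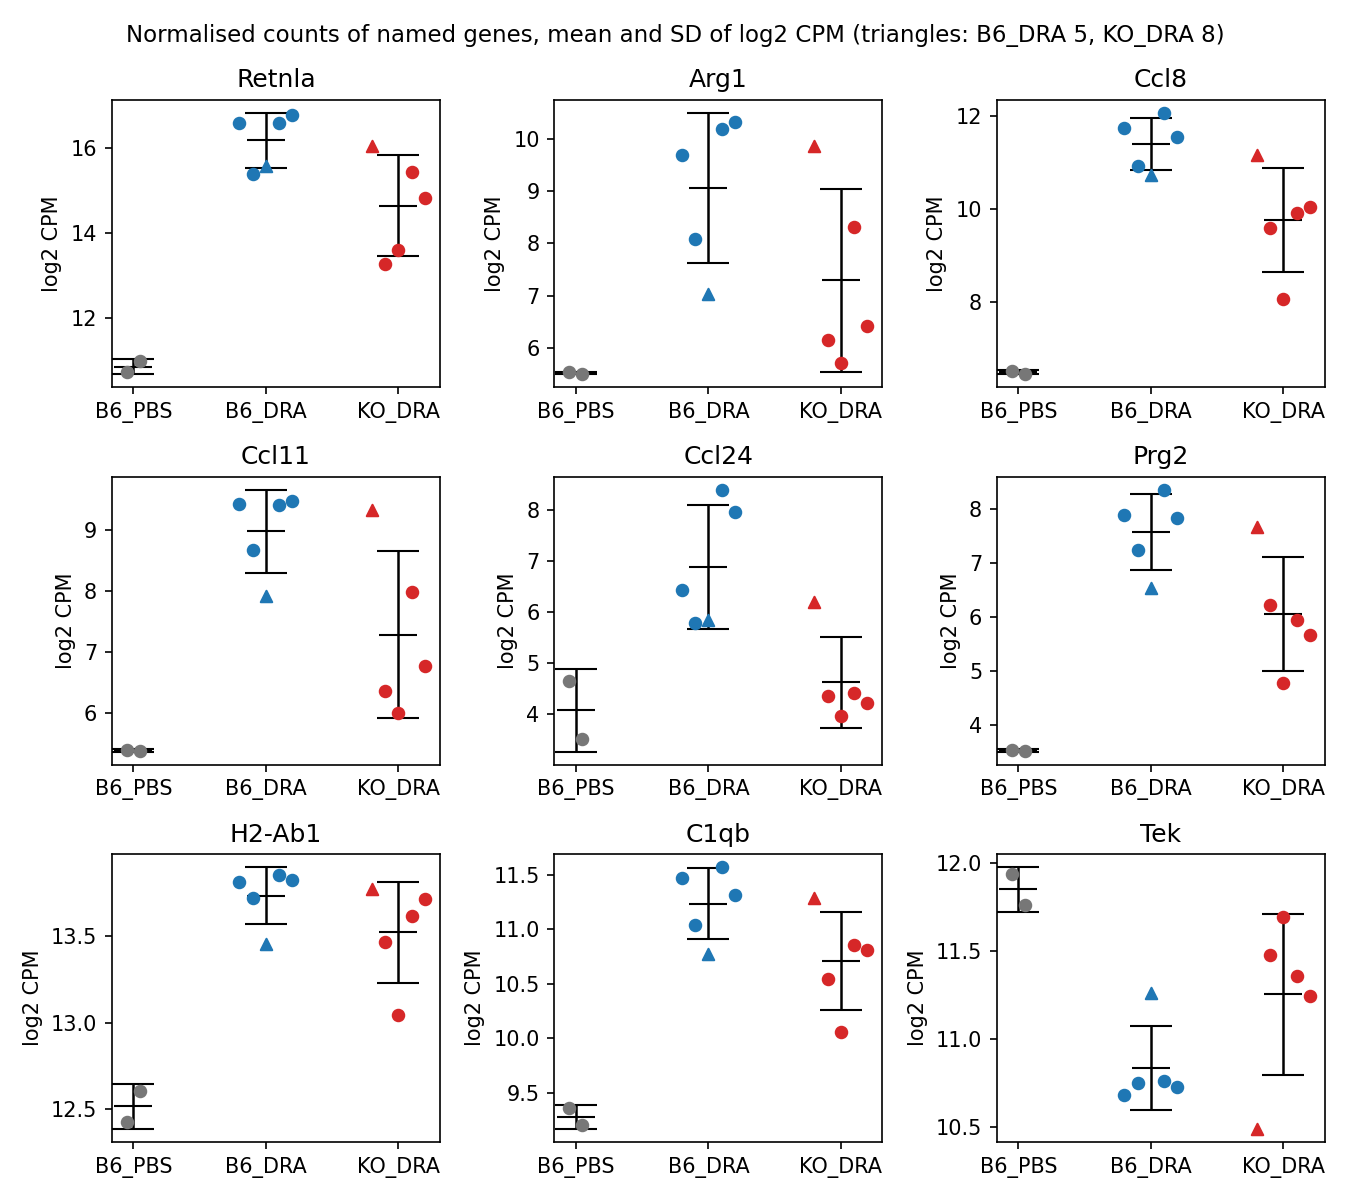
log2 CPM of 9 named genes (vertical) in each library by group, with the mean and SD of log2 CPM; triangles mark B6_DRA 5 and the library labelled KO_DRA 8. Ccl8 stood at 89 CPM in B6_PBS, 2892 in B6_DRA and 1075 in KO_DRA on average, and the library labelled KO_DRA 8 is the highest of its group for Ccl24.

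The second comparison set Chil4-deficient mice against wild type mice, both given allergens. Without Chil4-deficient mice given PBS, it cannot tell an altered response from a genotype difference present without allergen. No gene passed the test between KO_DRA and B6_DRA, and every direction here is drawn with the library labelled KO_DRA 8 in the KO_DRA group. The 5 genes with the smallest p were Scin, an actin-severing protein gene (log2 fold change -1.21, SE 0.292), Fosb (0.99, SE 0.245), the lectin gene Cd209e (-1.91, SE 0.484), Abcc8 (-1.74, SE 0.445) and Ccl24 (-2.37, SE 0.627), all with an adjusted p of 0.313 by edgeR. In KO_DRA the median counts of Abcc8, Cd209e and Ccl24 were 2, 5 and 9, near or under background, so the sizes of these 3 changes are uncertain. Ccl24 was 156.5 ± 128 CPM in B6_DRA and 29.8 ± 24.2 CPM in KO_DRA (SD, n = 5 each). Retnla had a log2 fold change of -1.29 (SE 0.503, adjusted p = 0.329 by edgeR), Arg1 -1.32 (SE 0.81), Ccl11 -1.25 (SE 0.572), Il33 -0.67 (SE 0.228), Il13 -0.60 (SE 0.452) and Il4 -0.48 (SE 0.558). Il5, with at most 11 counts, did not pass the filter.

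None of the 27 gene lists passed fry. The smallest p belonged to the eicosanoid pathway (fry adjusted p = 0.171), with 9 of 11 estimates lower, although the list ran higher with library size alone. In it Cysltr1, a leukotriene receptor gene, had a log2 fold change of -0.44 (SE 0.119) and Alox5 -0.33 (SE 0.112). Chemokines of type 2 inflammation followed (fry adjusted p = 0.29), with 9 of 10 estimates lower. Both lists had an unadjusted p under 0.05, the only 2 that did. At the same adjusted p stood Fc and C-type lectin receptors, with 7 of 8 estimates lower, type 2 cytokines, alarmins and their receptors, with 7 of 10 lower, complement, with 7 of 8 lower, and eosinophil markers, with 8 of 8 lower. Alternatively activated macrophage genes had 16 of 19 lower (fry adjusted p = 0.346) and interferon-stimulated genes 6 of 8 higher (fry adjusted p = 0.383), and every other list had a fry adjusted p of 0.421 or more. When adjusted over the list alone, 3 chemokine genes, 2 genes of alternatively activated macrophages, 1 eicosanoid gene and 1 lectin receptor gene were lower. These counts overlap. The 2 macrophage genes are Cd209e, which is also the lectin receptor gene, and Ccl24, which is also 1 of the chemokine genes. Both had median counts near or under background in KO_DRA. Camera with a preset correlation called 8 lists, and none with an estimated correlation (smallest adjusted p = 0.709).

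Of the 160 genes that rose with allergen in wild type mice, 154 had a lower estimate in KO_DRA than in B6_DRA, with a median of -0.38, and all 118 genes that fell had a higher estimate, with a median of 0.27. The B6_DRA libraries that picked these genes enter this comparison with opposite sign, which favours such directions even with no change. With library size alone, which raises the median gene of this comparison by 0.34, 91 of the 160 were lower and all 118 higher. Across genes, which are not independent replicates, the covariance of the allergen effect and the genotype effect was -0.393 (r = -0.861). Unchanged KO_DRA libraries simulated against the B6_DRA libraries gave a median covariance of -0.0356 (r = -0.117) and a lowest one of -0.129, but simulated genes leave out swings that many genes share in 1 animal. Of 100 ordered regroupings of the 10 allergen libraries, 6 reached the observed value, the real grouping included (furthest other -0.753). The B6_DRA libraries were also divided between the effects in all 20 ways, with effects taken as differences of mean log2 CPM. The median was then -0.393 and all 20 values were negative. The observed value used edgeR fold changes instead, so the equal -0.393 does not show how much the shared libraries contribute.

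**Figure D3:**
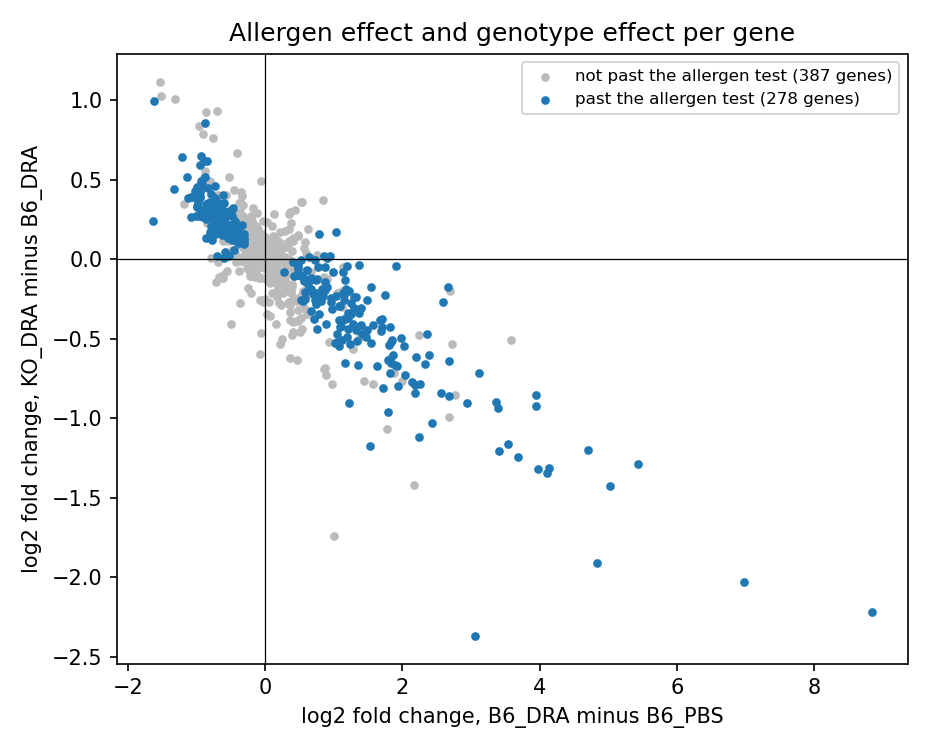
Log2 fold change of KO_DRA against B6_DRA (vertical) against that of B6_DRA against B6_PBS (horizontal), 1 point per gene, blue where the allergen test was passed. The points run from upper left to lower right (r = -0.861), and both axes share the B6_DRA libraries.

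The count of 0 came with 84 genes at an unadjusted p under 0.05, 36 higher and 48 lower, where chance gives 33.2; DESeq2 called 1 gene, Ccl24, which was lower (adjusted p = 0.0356), and limma-voom called 0. Without the library labelled KO_DRA 8, edgeR called 120 genes, 30 higher and 90 lower, and 6 lists were lower by fry: chemokines of type 2 inflammation (adjusted p = 0.028), the eicosanoid pathway (0.0365), alternatively activated macrophage genes (0.0366), eosinophil markers (0.0373), Fc and C-type lectin receptors (0.0441) and alveolar macrophage markers (0.0481).

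Of the type 2 genes fixed beforehand, without that library Arg1 fell by 2.48 on the log2 scale (adjusted p = 0.0421 by edgeR), Retnla by 1.74, Ccl11 by 2.11 and Il33 by 0.86, and Ccl24, near background in KO_DRA, also passed lower, while Il13 (adjusted p = 0.0584 by edgeR) and Il4 (adjusted p = 0.414 by edgeR) did not pass. Among the other genes called without that library, the next are examples chosen after their values were seen, on the log2 scale. Prg2 fell by 1.94 (adjusted p = 0.0344 by edgeR), Ccl8 by 1.92 and Cd80 by 0.91, while Tek rose by 0.60 and Fosb by 1.06. Of the 120 genes, 91 were also called in the allergen comparison, and all 91 ran against the allergen effect, a direction that the shared B6_DRA libraries favour. That library was singled out after its values were seen, and no other single library of the 2 groups moved the count from 0 when left out.

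The third comparison set Chil4-deficient mice given allergens against wild type mice given PBS, so genotype and treatment differ together. All 20 genes that passed rose. Retnla rose 17.7-fold (log2 fold change 4.15, SE 0.845, adjusted p = 0.0342), Ccl8 rose by 3.59 on the log2 scale, Ctla4 4.97-fold, Scin at least 2.06-fold over a B6_PBS level below background and Ccl20, a chemokine for CCR6-bearing lymphocytes, 3.70-fold. C1qa, C1qb and C1qc rose 2.54-fold, 2.80-fold and 2.44-fold. The class II genes H2-Ab1, H2-Aa, H2-Eb1 and H2-DMb2 rose 2.03-fold, 1.98-fold, 2.12-fold and 2.23-fold, and the integrin genes Itgb7 and Itga4 1.54-fold and 1.46-fold. Chil4 had a log2 fold change of 3.02 (SE 1.26, adjusted p = 0.158 by edgeR). The library labelled KO_DRA 8 stood at 255000 CPM of Chil4 and the other KO_DRA libraries at 11020 to 57360 CPM. The B6_PBS mean was 9123 CPM, so the size of this estimate leans on the library labelled KO_DRA 8.

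By fry, 7 lists were higher: adhesion and trafficking (3 of 23 genes past the test, 6 over the list alone, adjusted p = 0.0116), T cell markers (1 of 6, 5 over the list alone, 0.0116), MHC class II presentation (6 of 12, 11 higher and 1 lower over the list alone, 0.0116), the eicosanoid pathway (0 of 11, also over the list alone, 0.0202), complement (3 of 8, 5 over the list alone, 0.0241), monocyte and interstitial macrophage markers (3 of 15, also over the list alone, 0.0382) and type 2 chemokines (1 of 10, 2 over the list alone, 0.0382). The 3 genes past the test are the same in the complement list and the monocyte list: C1qa, C1qb and C1qc. For each of the 7 lists camera adjusted p = 0.494 with an estimated correlation, while camera with a preset correlation called 10 lists. Eosinophil markers did not pass (0 of 8 genes past the test, 6 higher over the list alone, fry adjusted p = 0.112). Rnase2a, at least 20.5-fold higher over a B6_PBS level below background, did not pass either (adjusted p = 0.0999 by edgeR). Its mean in KO_DRA was 683.5 CPM, and 305.1 CPM without the library labelled KO_DRA 8, so the size of its rise leans on that library.

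All 20 genes were also higher in B6_DRA against the same B6_PBS libraries, where independent lists of these sizes would share 4.81, but both comparisons use the same B6_PBS libraries, and with either B6_PBS library alone neither comparison called a gene, so an overlap free of that sharing is not given. The count fell to 0 without either B6_PBS library, KO_DRA 11 or KO_DRA 12, to 2 without KO_DRA 9 and to 9 without the library labelled KO_DRA 8, and it was 79 without KO_DRA 10; DESeq2 called 56, limma-voom 13, library size alone 4 and a fit of only the 2 groups 0, with 190 genes at an unadjusted p under 0.05. The 7 lists became 0 without B6_PBS 1, 1 without B6_PBS 2, 4 without KO_DRA 11 or KO_DRA 12 and 11 without KO_DRA 10.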

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

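The tests of the response size, of splits against counts of 0, of the Chil4 and Chil3 ratio and of the library size without Chil3, Chil4 and Retnla were chosen after their results were seen, as was leaving out 2 libraries together; splits that repeat the choice of a left-out library were added after the splits without that choice were seen. Among 122 named genes, 24 of 244 gene and group pairs held a library far from the other 4 of its group. Chance gives about 1 in 20 for unselected genes that vary independently. Many named genes were picked for their results, and genes move together within a library, so these flags are not separate outliers. B6_DRA 5 held 7 of them as the lowest and 6 as the highest of its group. B6_DRA 5 was the lowest of its group in log2 CPM for Ctla4 (5.72), Itgax (8.05), Cd83 (8.71), Il33 (10.94), H2-Eb1 (12.44), Cd68 (10.33) and Il6 (4.19), and the highest for Tek (11.26), Bmp6 (10.51), Thbd (12.59), Kitl (10.90), Timp3 (12.33) and Smad7 (10.54). The library labelled KO_DRA 8 was the highest of its group for Ccl24 (6.27) and Cd80 (7.80) and the lowest for Gata2 (8.05) and Bmp6 (9.13). It also had the highest Chil3 count (145039), Chil4 count (111850) and mean negative control count (4.12) of KO_DRA. B6_DRA 3 was the lowest for C5ar1 (7.49), Cd27 (4.49) and Klrk1 (6.87). KO_DRA 10 was the lowest for H2-DMb2 (8.96) and H2-Aa (14.19) and the highest for Tlr3 (7.85), and KO_DRA 9 the lowest for Csf3r (7.10). Gusb, a lysosomal enzyme gene in the housekeeping block outside the tested genes, was higher in B6_DRA than in B6_PBS by 1.01 on the log2 scale (SE 0.307, unadjusted p = 0.00645); the authors' factors leave it out.

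The genotype comparison called 0 genes with the library labelled KO_DRA 8 and 120 without it. Depth is argued against, since 100 genes were called without it and 0 with it after every library was thinned to 320290 counts. A candidate explanation is that KO_DRA 8 and B6_DRA 5 carry each other's labels: off the allergen direction, a placing by the other 8 libraries put KO_DRA 8 with B6_DRA and B6_DRA 5 with KO_DRA, with 7 of those 8, all but KO_DRA 11, placed in their own group, the fewest set beforehand as enough. Animals may instead differ in the size of their allergen response. The deviation of KO_DRA 8 from its group followed the allergen effect across genes (r = 0.813). Exchanged labels would give such an r too, so it cannot tell these explanations apart. Deviations of KO_DRA 10 (-0.85), B6_DRA 5 (-0.779), KO_DRA 9 (-0.62), B6_DRA 6 (0.57) and B6_DRA 7 (0.551) also followed it in either direction. Each was taken from the mean of the group's other libraries. That mean holds KO_DRA 8 for KO_DRA 9 and 10, and B6_DRA 5 for B6_DRA 6 and 7. These values therefore partly restate KO_DRA 8 and B6_DRA 5. Whether a strong response alone also shifts the placing was not tested. Exchanged labels and differing response size both stay open. An effect of genotype on response size, or a genotype difference present without allergen, stays open too. The groups were kept as labelled.

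With all 10 allergen libraries the real split called 0 genes and 0 lists, which all 100 drawn splits reach by construction, so these splits say nothing on chance; the highest other split called 313 genes and 19 lists, which points to a structure of the samples. In that split KO_DRA 8 and B6_DRA 5 trade groups, which parts the libraries along the first principal component on which these 2 stand out, so its count restates that observation and supports no cause of it. The 120 genes without KO_DRA 8 were reached by 4 of 100 drawn splits of the 9 remaining libraries (highest other 280), but that library was chosen for what its absence does to the count. With the choice repeated in each of 100 splits of the 10 libraries, leaving out whichever 1 gave the most genes, 14 reached 120 (highest other 304), so chance is not excluded. The covariance of -0.393 was reached by 6 of 100 ordered splits (furthest other -0.753), so chance is not excluded there either. A first draw, which left out the mirror of each split although the covariance depends on which part stands for B6_DRA, gave 3 and was replaced after it was seen.

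Chil4 counts followed Chil3 counts in every library. A loss of Chil4 RNA read by a probe specific to Chil4 is argued against, since the log2 ratio was only 0.06 lower in KO_DRA (difference -0.0557), where a loss of most of that RNA needs -1 or less. The SD of the log2 ratio over 12 libraries, 0.0598, is consistent with a Chil4 probe that also reads Chil3 RNA. An altered gene whose RNA persists and moves with Chil3 stays open, as no value here separates the 2 RNAs.

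The split of allergen calls turned from 160 higher and 118 lower to 57 and 222 under library size alone. With Chil3, Chil4 and Retnla left out of the library size the lower calls came to 161, with 138 higher, which is consistent with a few abundant genes taking counts from the rest. No biological explanation was tested for this pattern.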

How the results depend on the processing

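Alternatives chosen after seeing the data were leaving out KO_DRA 8 and B6_DRA 5 together, sample quality weights, and the library size without 3 genes; the first 2 act on libraries for lying far from their group, so their larger counts are no independent evidence. Causes were tested, as given above, only for the genotype count without KO_DRA 8 and the split of the allergen calls with library size alone. No cause was tested for the other changes below. B6_DRA against B6_PBS kept its count within 1.5 times of 278 genes except with quality weights (430) and left-out libraries (0 to 345); its 14 lists became 5 with library size alone, 0 with camera and an estimated correlation and 7 to 16 with a library left out. KO_DRA against B6_DRA called 0 genes except with DESeq2 (1), both libraries left out (257), quality weights (179) and single libraries left out (0 to 120), and 0 lists except with camera preset (8), both left out (16), weights (12) and single libraries left out (0 to 6). The log2 fold change of Chil4 KO_DRA minus B6_DRA kept its sign, passing the threshold with both left out (-2.53), with weights (-2.23) and without KO_DRA 8 (range over left-out libraries -2.27 to -0.64). KO_DRA against B6_PBS moved from 20 genes to 4 with library size alone, 56 with DESeq2, 13 with limma-voom, 0 with the 2 groups alone, 37 with both left out, 176 with weights and 0 to 79 with a library left out, and from 7 lists to 0 with camera and an estimated correlation, 11 with weights and 0 to 11 with a library left out. The covariance stayed negative throughout, from -0.611 to -0.295 over left-out libraries. Signs of named genes turned only where not called: with library size alone for Cxcr5 B6_DRA minus B6_PBS (-0.0188), where Cdc20 (-0.39) and Top2a (-0.55) turned too, and for Alox5 KO_DRA minus B6_DRA (0.00592), where Top2a (0.12) and H2-Eb1 (0.0847) turned too; with the 3 genes out of the library size for Top2a B6_DRA minus B6_PBS (-0.0646); and with a library left out for Cdc20 B6_DRA minus B6_PBS (-0.22 to 0.88), Top2a B6_DRA minus B6_PBS (-0.15 to 0.37), Top2a KO_DRA minus B6_PBS (-0.36 to 0.16), Cdc20 KO_DRA minus B6_PBS (-0.71 to 0.39) and Cxcr5 KO_DRA minus B6_DRA (-0.0104 to 0.32). Library size alone moved the median gene by -0.63, 0.34 and -0.29 in the 3 comparisons, and housekeeping scaling by 0.11 in the last. Without a B6_PBS library, the other is assumed to vary like the other groups. The pseudocount of 10 was not run, as the values are counts. No paired analysis was possible because no replicate number is shared between groups. In the deposited counts, negative controls of 2.75 to 5.63 limit folds of genes near background.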

Other observations

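The lists and the test below were fixed before the data were examined, and none was chosen after its result was seen. In B6_DRA against B6_PBS, TGF-beta and growth factor signalling had 1 gene higher and 5 lower of 14, or 1 and 6 when adjusted over the list alone (fry adjusted p = 0.0697). Toll-like receptor and signalling genes had 5 higher and 2 lower of 14, also when adjusted over the list alone (0.17), and alveolar macrophage markers 3 higher of 9, also over the list alone (0.192). Interferon-stimulated genes had 1 higher and 4 lower of 8, also over the list alone (0.223), NF-kB and MAP kinase genes 1 and 1 of 9, or 0 and 1 over the list alone (0.392), and type 1 immunity 1 and 2 of 9, also over the list alone (0.686; median log2 fold change 0.14 but test direction lower).

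Matrix genes had 3 higher and 5 lower of 16, also when adjusted over the list alone (fry adjusted p = 0.569; median log2 fold change -0.17, mean 0.56, test direction lower). IL-1, inflammasome and proinflammatory cytokine genes had 3 higher and 2 lower of 15, or 2 and 0 over the list alone (0.964; median -0.19, mean 0.15, test direction higher). Mast cell and basophil markers had 1 lower of 8, or 0 over the list alone (0.96; median 0.16, test direction lower), and the 1 neutrophil marker higher did not pass over the list alone (median 0.15, mean -0.12). No member passed among 4 B cell markers (0.338; Fcer2a log2 fold change 1.13, SE 0.613), 3 natural killer and cytotoxic markers (0.338; Gzma -0.63, SE 0.35) or 3 proliferation genes (0.544; Cdc20 0.25, SE 0.321). With library size alone the B cell, IL-1, Toll-like receptor and proliferation lists turned lower, and with housekeeping scaling type 1 immunity, NF-kB and mast cell lists turned higher, with no call in either.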
